A study of Homo sapiens with 2 samples.

How the data were processed

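Binding of 2 human transcription factors to DNA was measured on universal protein-binding microarrays, 1 array per protein. The proteins were SIX6, a homeodomain protein of the sine oculis (SIX-type) family, and TFAP2A, a member of the AP-2 family. Per the labels, each was a full-length protein fused to GST, made in E. coli and purified on GST resin, and was applied to the array at 100 nM. Bound protein was read, per the labels, with an antibody against GST that carried the Alexa488 dye. Such an array carries double-stranded probes in which every 8-mer lies in many sequence contexts. Each array had 45220 spots, of which 41944 held the probes that cover all 8-mers. A further 1856 spots held 892 control sequences, and 1420 spots had no sequence in the files. A probe was 60 bases long, with a variable part of 36 bases at the free end and 24 bases common to all probes next to the glass. No repeat array and no array without protein was analysed here.

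The Alexa488 intensity per spot was used as deposited, on a linear scale. Scanner, scan settings, background subtraction and the joining of scans are not given in the sources used here. The intensities kept a gradient across each array, and no spot carried a flag. The Cy3 column, which on such arrays can report the amount of DNA per spot, held the value 1 in every row, so probe intensities were not corrected for DNA amount here. For each of 32896 8-mers, with reverse complements joined, the authors deposited a median intensity, an enrichment score (E-score) and a Z-score. The software behind these scores is not given in the sources used here. Their construction was checked from the values. Dividing each spot's intensity by the median of a window of 15 by 15 spots gave 80.4% of the deposited medians on the SIX6 array and 82.0% on the TFAP2A array within 0.01%, up to 1 common factor. E-scores recomputed from these normalised intensities correlated with the deposited scores at r = 0.993 for SIX6 and r = 0.988 for TFAP2A across 8-mers. The E-score is a rank statistic that sets the brighter probes with an 8-mer against the brighter probes without it. It does not depend on the intensity scale of the array.

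Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The 8-mers were read from bases 2 to 36 of each probe, counted from the free end. An 8-mer counted as bound when its deposited E-score was above 0.45, a threshold fixed before the data were examined. The same holds for the 28 sequence classes, the comparisons described in the next sentences and the rule for named items, but not for several tests of the closing section, which are named there. A class was described by its median E-score and by the percentile of that median among 10000 random lists of 8-mers of the same size and the same numbers of G and C. Members of a class share a core, while the 8-mers of a random list need not, so class medians can spread more widely. The percentile is thus a rank and not a test. Single-base changes were measured as log2 of the median normalised intensity of the changed 8-mer over that of the best 8-mer, with 95% bootstrap intervals from 2000 resamples of probes. Spacers and flanks were measured as mean log2 normalised intensity minus the array median. A 6-mer regression by ordinary least squares used the variable part of each probe, with R2 from 5-fold cross-validation. Shares of 8-mers have 95% Wilson intervals. Those intervals treat 8-mers as independent, which overlapping 8-mers are not. With 1 array per protein there was no test across samples, so no p-value is given. Intervals and standard errors (SE) cover the spread between probes of 1 array only, and the number of arrays limits the precision.

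The named 8-mers were, per array, the 10 with the highest E-score and the 5 highest without a class of the array's own protein, with the best member of each class. The rule also took the 4 smallest and 4 largest falls after single-base changes, the 5 highest and 5 lowest 6-mer coefficients, and the 4 highest and 4 lowest spacers or flanks. Up to 5 8-mers above the threshold on both arrays were to be named, and there were none. Best members are left out for most classes that had no bound member on the TFAP2A array.

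The steps were tested on simulated arrays that kept the real probe sequences, layout and gradient, with probe noise of SD 0.25 on the log2 scale. With 8-mers raised by a log2 effect of 1, 100% of the 66 raised 8-mers passed an E-score of 0.45 in the SIX6 simulation and 100% in the TFAP2A simulation, each over 32896 8-mers. With an effect of 0.5, 0% of 67 passed for SIX6 and 1.49% of 67 for TFAP2A. On the real arrays the highest 8-mer lay 0.96 log2 over the middle one for SIX6 and 0.68 for TFAP2A. CCCCCCCA passed on the real TFAP2A array at 0.29, with an SD of 0.51 over its probes. The simulated setting thus differs from the data and does not give their sensitivity. No unchanged 8-mer passed among the 30021 of the SIX6 simulation or the 30010 of the TFAP2A simulation that shared no 7 bases with a raised one. In the simulated regression, which used the probe sequences of the SIX6 array, all 40 coefficients set away from 0 lay over 3 SE from 0, as did 3 of 2040 coefficients set to 0.

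The alternatives were other E-score thresholds, the Z-score, recomputed E-scores, intensities before normalisation, odd or even rows of the array, random lists not matched on G and C, means in place of medians and the reverse, and 5-mers. Sites next to the common end or second sites were also left out. After the data had been seen, 4 kinds of alternative were added. These were a second seed 8-mer per protein, removal of the printed strand's base numbers, disjoint rows for the 2 arrays, and sites ranked, or 8-mers picked, on one set of rows and measured on the other. The alternative that leaves out flagged probes was not run because no spot had a flag. The comparison of the 2 orientations of control sequences was made after the data had been seen and is given as values only. Probes are synthetic sequences, so no genomic position applies.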

Results

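Binding of SIX6 and of TFAP2A to all 8-base DNA sequences was measured on 1 universal protein-binding microarray each, at 100 nM protein. SIX6 is a homeodomain protein with a role in eye and pituitary development, and TFAP2A is an AP-2 family protein with a role in neural crest and epidermal development. The series concerns the prediction of binding changes caused by sequence variants, so the comparisons ask which sequences each protein bound and how single bases moved the signal. Median intensity over the 41944 probes was 31869 on the SIX6 array and 31306 on the TFAP2A array, with ranges from the 5th to the 95th percentile of 14063 to 52064 and 20075 to 43012. Each 8-mer lay on a median of 36 probes, from 16 to 45. The gradient across the SIX6 array was steep, with medians of 70 blocks of spots between 6313 and 38874, against 18950 and 36230 on the TFAP2A array. After normalisation for position, duplicate spots of the control sequences had an SD of 0.11 log2 on the SIX6 array and 0.12 on the TFAP2A array. The SD over probes was 0.32 and 0.26.

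SIX6 bound 65 8-mers above an E-score of 0.45, and most of them held the bases TATC or its complement GATA. The highest was the palindrome GGATATCC, with an E-score of 0.491 and a median intensity of 60706, 1.94-fold over the middle 8-mer of the array (19 probes). It was followed by GGGTATCA with 0.489, ATGATACC with 0.481, GGGGGATA with 0.481 and GATACCCC with 0.480. The others among the first 10 were GATATATC, GATATCCA, ATCGATAC, CATGATAC and AGGGTATC, with E-scores between 0.478 and 0.480 and median intensities 1.58-fold to 1.68-fold over the middle. The 5th of the 8-mers without a SIX-type class, after GGATATCC, GGGGGATA, GATATATC and GATATCCA, was TGATATCA with 0.476.

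TFAP2A bound 37 8-mers above the same threshold, and these were rich in C and G, with a median of 7 such bases against 3 in the SIX6 set. The highest were CCCCCAGG with an E-score of 0.493, CCCCAGGG with 0.493, CCCCCGGG with 0.492 and CCTCAGGC with 0.491. The last holds the AP-2 sequence GCCTGAGG on its other strand. CCCTCAGG, CCCCAGGC, CCGGGGGC, CCCCGGGC, CCCCGGGG and CCCCGAGG completed the first 10, between 0.484 and 0.491. The rise in intensity was smaller than for SIX6: the highest median was 49767, for CCCCAGGG, 1.60-fold over the middle 8-mer. The highest 8-mers without an AP-2-type class were CCCCCCCA with 0.463, CCTCGAGG with 0.463, CCCCCCAG with 0.461, CCCCCCCC with 0.460 and GGGGGGCA with 0.458.

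On the SIX6 array 96 8-mers had an E-score above 0.45 from odd rows and 92 from even rows, and 34 passed in both. On the TFAP2A array the numbers were 56 and 44, and 23 passed in both. At the looser 0.40, 62 of the 65 SIX6 8-mers and 34 of the 37 TFAP2A 8-mers passed in both sets of rows. Those 65 and 37 were picked on all rows together, which raises their scores in each set. These counts are therefore no independent check. Across all 8-mers the scores from odd and even rows correlated at r = 0.513 for SIX6 and r = 0.321 for TFAP2A. When intensities were shuffled over probes 20 times, the highest E-score was 0.378 on the SIX6 array and 0.383 on the TFAP2A array. From intensities before normalisation 33 SIX6 and 24 TFAP2A 8-mers passed 0.45. Folds are ratios of the deposited 8-mer medians, and no background was subtracted here. Those medians followed medians recomputed after normalisation for position at rho = 0.987 for SIX6 and 0.986 for TFAP2A. Before normalisation the values were 0.720 and 0.773. The 153 spots that the files name as negative controls, whose sequences were not used here, had a median of 76.5% of the median of the probes around them on the SIX6 array and 46.8% on the TFAP2A array. The 604 dark corner spots had 96.5% and 61.0%.

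No 8-mer was above 0.45 on both arrays, where 0.0731 would be expected if the 65 and 37 were independent of each other. The SIX6 set had a median E-score of 0.172 on the TFAP2A array, with a range from -0.0205 to 0.435. The TFAP2A set had a median of -0.0680 on the SIX6 array, with a range from -0.298 to 0.346. Of all 32896 8-mers, 950 had an E-score at least 0.30 higher on the SIX6 array and 873 at least 0.30 higher on the TFAP2A array. Among the bound sets these were 30 of 65 and 31 of 37.

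Over all 8-mers the arrays were not independent. Across 8-mers, which share probes and are not independent replicates, E-scores correlated at Pearson r = 0.479 and Spearman rho = 0.492. At a threshold of 0.40, where 315 8-mers passed for SIX6 and 105 for TFAP2A, 3 passed on both against 1.01 expected from independent sets. All 3 held GGGGG on one strand: GGGGGATA with 0.481 on the SIX6 array and 0.435 on the TFAP2A array, AGGGGGAT with 0.441 and 0.432, and ATACCCCC with 0.416 and 0.442. They were named after their values were seen. Where the 2 arrays were scored from disjoint rows, r was 0.229 and 0.223.

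**Figure D1:**
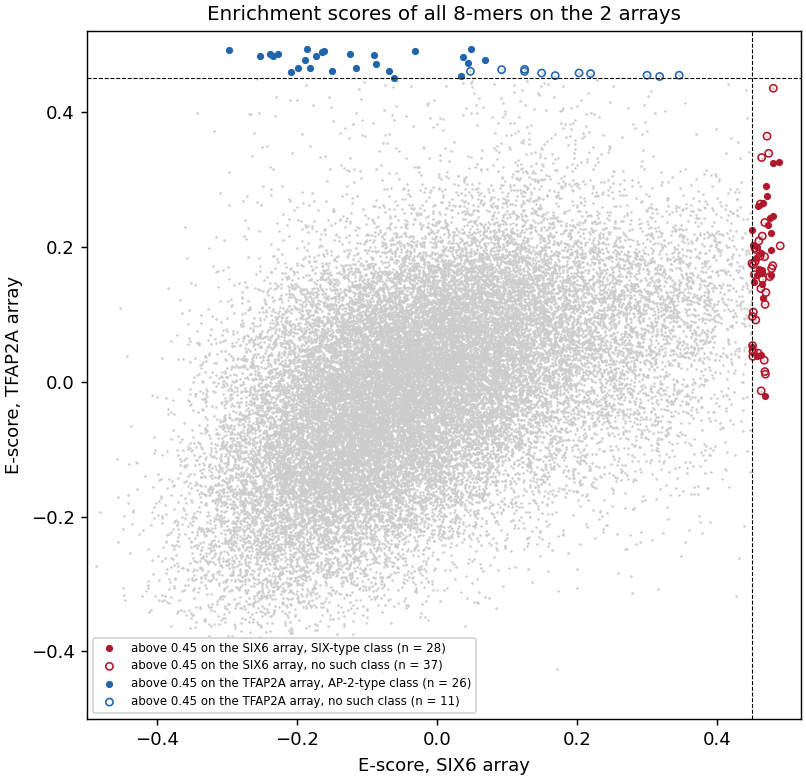
E-score of each 8-mer on the SIX6 array (horizontal axis) and on the TFAP2A array (vertical axis), with dashed lines at 0.45. Red marks the 65 8-mers above 0.45 for SIX6 and blue the 37 for TFAP2A, filled where they hold a preset class of the protein (28 and 26), and no point lies above both lines.

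The SIX-type classes, fixed from known sites of the family, stood high on the SIX6 array. Of the 48 8-mers with TGATAC, 19 were bound, with a median E-score of 0.438 over the class. GGTATC had 14 of 48 bound and a median of 0.421, and the shorter GATAC had 28 of 256 bound and a median of 0.387. All 8-mers with TGATAC or GGTATC also hold GATAC on one strand, so the 3 classes are nested. The best member of all 3 was GGGTATCA. Each of the 3 medians lay above every one of the 10000 random lists matched on G and C. CACCC, GGGGG and AGATAA, fixed as unrelated, also lay above every such list on this array. That rank alone therefore does not single out SIX-type sites. Together the SIX-type classes held 28 of the 65 bound 8-mers, or 43.1% (Wilson 95% interval 31.8 to 55.2), against 1.09% of all 8-mers. The share was 30.5% above 0.40 and 26.2% by Z-score above 4, in larger sets that include the same 65 8-mers.

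Other SIX-type sequences were weaker or did not stand out. TGACAC had no bound member, yet its median of 0.236 was above all random lists, and its best member was ATGACACC with 0.427. GAAACC, part of the MEF3 site of SIX-type proteins in muscle genes, had no bound member and a median of 0.0184, at percentile 94.6, with ATGAAACC the best at 0.255. TCAGGTT had none and a median of 0.0521, at percentile 80.2, with AACCTGAT at 0.306. Among sites of other homeodomain proteins, TAATCC, the site of bicoid-type and PITX proteins, had no bound member but a median of 0.229 above all random lists. Its best member GATAATCC, with 0.360, also holds GATA. TAATTA, the usual homeodomain site, had a median of 0.0414 at percentile 60.9, with GTAATTAC at 0.263.

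Of the 37 SIX6 8-mers that hold no SIX-type class, many held the palindromic core GATATC. This core and those that follow were picked after the values were seen. Of its 26 8-mers 15 were bound, with a median of 0.456 on the SIX6 array and 0.118 on the TFAP2A array. GATAC, GATATC and GATCC together were found in 48 of the 65 bound 8-mers, and TATC in 56.

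The AP-2-type classes with a 3-base spacer stood high on the TFAP2A array but were split inside. GCCNNNGG, the larger part of the AP-2 site, had 13 of 64 8-mers bound and a median of 0.157. CCCNNNGG had 13 of 58 bound and a median of 0.202. Both medians lay above all random lists. The single 8-mers GCCTGAGG, GCCCGAGG and GCCTCAGG had E-scores of 0.491, 0.483 and 0.483. Within GCCNNNGG the scores reached from -0.329 to 0.491. GCCNNGG, with a shorter spacer, had a median of -0.0554, at percentile 99.7 of matched lists, 0.07 of unmatched lists and 85.9 by Z-score, and 6 of 122 members bound, with CCCCAGGC the best. All 6 also held GCCNNNGG, and the 106 members without a class of 3-base spacer had a median of -0.0985 and none bound. All AP-2-type classes together held 26 of the 37 bound 8-mers, or 70.3% (Wilson 95% interval 54.2 to 82.5), against 0.693% of all 8-mers. At a threshold of 0.40 they held 37 of 105, or 35.2%, and GGGGG was found in 71 of the 105. Of the 68 8-mers between both thresholds, 55 held GGGGG and 11 an AP-2-type class.

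Each family was the control of the other. On the SIX6 array no AP-2-type 8-mer was bound and the family's median was -0.162. CCCNNNGG was at percentile 98.9 of matched lists there, 1.18 of unmatched lists and 85.2 by Z-score, and GCCNNNGG at 0.41 of matched lists. On the TFAP2A array no SIX-type 8-mer was bound, but 3 of the classes lay above all random lists there: TGATAC with a median of 0.140, GGTATC with 0.135 and GATAC with 0.0961. The first 2 lie within GATAC, so these are not separate results. TCAGGTT was at percentile 99.3 on that array, or 96.3 by Z-score. Of the classes fixed as unrelated, the run GGGGG was the one with many bound members for TFAP2A, 16 of 208, with a median of 0.379. On the SIX6 array 2 of the 208 were bound, with a median of 0.0946, also above all random lists. CACCC, another C-rich class, lay above all random lists on both arrays with medians of 0.0923 and 0.0990. The run AAAAAA lay below all random lists on both, at -0.154 for SIX6 and -0.0613 for TFAP2A, where it was at percentile 2.54 of unmatched lists. On the SIX6 array the best members of these classes were GGGGGATA and GGGTGATA with 0.417, which both hold GATA, and AAAAAATA with 0.0708. On the TFAP2A array they were CCCCCAGG, CCACCCCC with 0.421 and GCAAAAAA with 0.183.

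No member of the remaining classes was bound by SIX6. AGATAA, a GATA factor sequence, had a median of 0.155 above all random lists, with AGATAACG at 0.308. TATAAA had 0.116 at percentile 99.5 and TATATAAA at 0.358. GGGCGG had -0.0682 and ATCCGCCC at 0.299, and CGCG had -0.102 and CGCGATAC, which holds GATAC, at 0.379. Both stood at the top of the lists matched on G and C, at percentiles 99.99 and 99.9, but at 13.5 and 0 of unmatched lists. CACGTG, TGACGTCA, CCGGAA, TGACAG, TTTATGG and CACTTAA lay between percentiles 6.61 and 93.3, with CCGGAA at 2.43 of unmatched lists and 1.34 by Z-score. Their best members CACGTGTC, TGACGTCA, ATCCGGAA, ATGACAGA, ATTTATGG and TCACTTAA had E-scores from 0.0220 to 0.306. AAACAA had a median of -0.0610 at percentile 0.16, or 20.1 of unmatched lists, with GTTGTTTA at 0.191.

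On the TFAP2A array 1 of the 626 8-mers with CGCG was bound, CCCGCGGC with 0.460, although the class median of -0.197 was below all random lists. GGGCGG had a median of 0.0152 above all matched lists but at percentile 79.3 of unmatched ones, no bound member, and CCGCCCCC at 0.411. AGATAA had 0.0866 at percentile 98.2, or 51.6 by Z-score. TAATTA and TAATCC were at percentiles 87.0 and 87.8, against 98.0 and 99.6 of unmatched lists and 98.3 and 98.6 by Z-score. TGACAG was at 0.52, and TATAAA at 0.45 of matched and 46.9 of unmatched lists. TGACGTCA, CCGGAA, CACGTG, AAACAA, TTTATGG and CACTTAA lay between percentiles 5.58 and 65.8, and none had a bound member. Of unmatched lists CACGTG was at 0.21 and CCGGAA at 0.01.

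The 8-mers 1 base away from the best SIX6 8-mer differed in signal by position, with the lowest signal after changes in the centre of the site. GGATATCC is its own reverse complement, so its changes form 12 distinct 8-mers, counted from 1 at the 5′ end as written. It was picked on these same probes and had the highest median of the array, so every change had to be a fall, and the intervals do not cover that choice. All 12 had an interval below 0, with a median change of -0.66 on the log2 scale. In a split chosen after the values were seen, the 8-mer with the highest E-score in 1 set of rows was measured in the other. TATCGATA, picked on odd rows, had a median change of -0.06 with no interval of 12 below 0 (7 probes with the start), and GATCCCCC, picked on even rows, -0.09 with 1 of 24 (21 probes). Both splits changed the start as well as the rows, so the falls from GGATATCC itself were not measured apart from that choice. Its E-score was 0.491 from odd rows and 0.489 from even rows. The size of its falls is still not a measure free of that choice. The largest fall was that of T4C, which changed the signal by -0.96 (95% interval -1.15 to -0.78), followed by T4A with -0.95, A3C with -0.78 and A3T with -0.72. The smallest falls were at the ends, with G1T at -0.28 (-0.58 to -0.10), G1A at -0.33, G1C at -0.39 and G2T at -0.40. A3G, which leads to the GGTATC class, lowered the signal by 0.40 and kept an E-score of 0.466. In all, 3 of the 12 changed 8-mers stayed above 0.45. With sites next to the common end left out, 7 of the 12 had an interval below 0. The median change was then -0.60, with 10 probes for the start. From GGGTATCA, a second start chosen after the values were seen, 17 of 24 changes had an interval below 0, with a median of -0.57, and 7 intervals held 0, those of G1A, G1C and G1T among them.

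Changes in the best TFAP2A 8-mer differed in effect by position. Of the 24 changes in CCCCCAGG, 19 had an interval below 0, with a median of -0.35. That start was also picked on the same probes. Picked on odd rows and measured on even rows, the start was CCCCGGGG, with a median change of -0.28 and 1 of 12 intervals below 0 (11 probes with the start). Picked on even rows and measured on odd rows it was CCCCCAGG again, with -0.24 and 8 of 24 (20 probes). The size depended on the start: from CCCCAGGG, the 8-mer with the highest median intensity, the median change was -0.59. The largest falls were in the C bases at positions 2 and 3, where C2G changed the signal by -0.70 (-1.02 to -0.52), C3G by -0.66, C2T by -0.59 and C2A by -0.56. The 4 changes with the smallest falls or none had intervals that held 0: C4T at 0.08 (-0.44 to 0.23), A6G at 0.06, A6C at -0.11 and C1G at -0.11. After 6 of the 24 changes the E-score stayed above 0.45. From GCCTGAGG, chosen as a second start after the values were seen, 15 of 24 changes had an interval below 0. The largest were G8C at -0.63 and G7C at -0.56, while A6G at 0.04 and G5C at -0.04 had intervals that held 0.

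**Figure D2:**
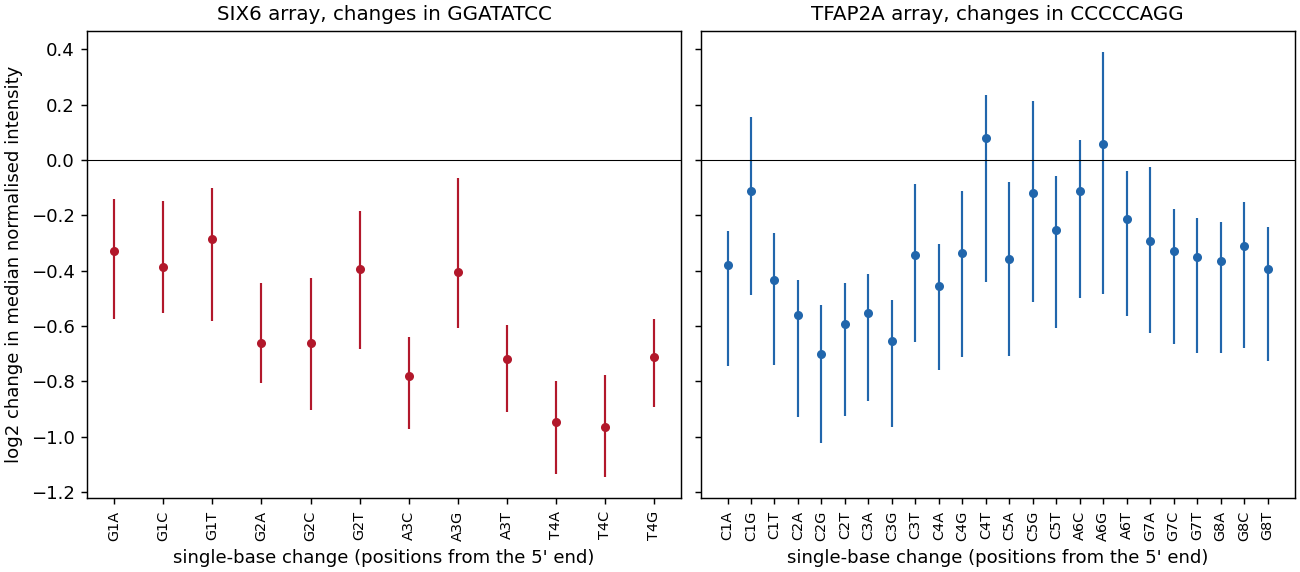
Log2 change in median normalised intensity (vertical axis) after each single-base change in the best 8-mer of the SIX6 array (left, 12 distinct changes) and of the TFAP2A array (right, 24 changes). Points are estimates and lines are 95% bootstrap intervals over probes, and the falls reach -0.96 on the left and -0.70 on the right.

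Probes with the 9-base AP-2 site GCCNNNGGC differed in signal by the 3 bases of the spacer. The 32 distinct 9-mers lay on 8 to 10 probes each. On the TFAP2A array the highest mean log2 intensity over the array median was that of GCCTCAGGC, 1.02 ± 0.75 (SD, 8 probes). GCCCCGGGC followed with 0.91 ± 0.67, GCCCCAGGC with 0.89 ± 0.70 and GCCCGAGGC with 0.84 ± 0.69. The lowest were GCCACCGGC with -0.18 ± 0.30, GCCAATGGC with -0.18 ± 0.19, GCCATCGGC with -0.14 ± 0.35 and GCCCTCGGC with -0.13 ± 0.20. On the SIX6 array the same 4 highest and 4 lowest differed by 0.03.

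The mean of the 4 highest minus that of the 4 lowest was 1.07 (SE 0.13), but the sites were picked on these same probes. When ranked on odd rows and measured on even rows the difference was 0.28, and 0.77 the other way round, so the order of single spacers rests on few probes. Forms of the site were compared after the values were seen. A spacer of 3 bases gave a mean of 0.29 (SE 0.04, 270 probes), 4 bases gave 0.15 (SE 0.03) and 2 bases gave -0.14 (SE 0.02). Some sites with a 4-base spacer also hold CCCNNNGGC, with a 3-base spacer, on one strand. These were not set apart, so 0.15 does not measure a 4-base spacer alone. With C as the first base, CCCNNNGGC had 0.36 (SE 0.02) and CCCNNNGGG 0.30 (SE 0.03). With A or T as the first base, ACCNNNGGC had 0.00 (SE 0.01) and TCCNNNGGC 0.01 (SE 0.01).

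**Figure D3:**
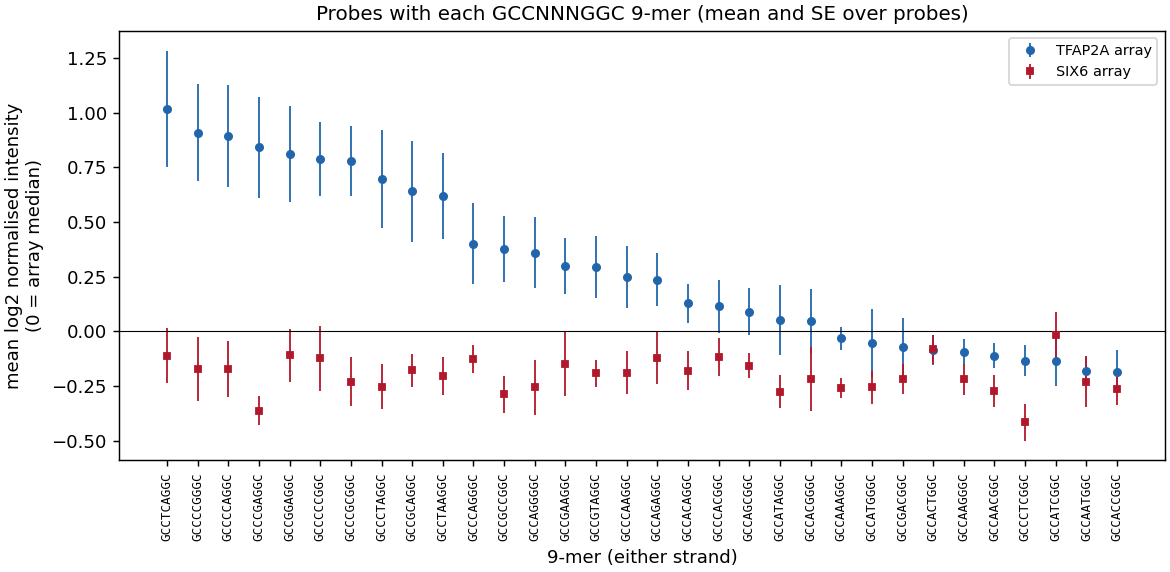
Mean log2 normalised intensity, with 0 at the array median, of probes with each of the 32 GCCNNNGGC 9-mers on the TFAP2A array (blue circles) and the SIX6 array (red squares), with SE over 8 to 10 probes. The 9-mers are ordered by the TFAP2A mean, from 1.02 down to -0.18, and the SIX6 means do not follow that order.

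The SIX6 signal of probes with the SIX-type core TGATAC differed by the bases beside it. A C after the core gave the highest values: the mean was 0.69 (SE 0.04, 155 probes), against 0.46 with A, 0.44 with G and 0.45 with T (SE 0.03 each). By the bases on both sides, the highest were ATGATACC with 0.73 ± 0.48 (SD, 41 probes), GTGATACC with 0.73, TTGATACC with 0.68 and CTGATACC with 0.66. The lowest were TTGATACT with 0.32 ± 0.33 (34 probes), CTGATACG with 0.33, TTGATACA with 0.37 and CTGATACA with 0.42. The 4 highest exceeded the 4 lowest by 0.34 (SE 0.05) on the SIX6 array and by 0.15 on the TFAP2A array. These flanks were picked on the same probes. In a split chosen after the values were seen, the SIX6 difference was 0.25 when ranked on odd rows and measured on even rows, and 0.37 the other way round. Before the core, A gave 0.60 and C gave 0.45 (SE 0.04 and 0.03).

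A regression on 6-mer numbers, the class of model that the series concerns, described the SIX6 array better than the TFAP2A array. R2 by cross-validation was 45.4% for SIX6, from 43.6% to 46.2% over the 5 folds, and 14.8% for TFAP2A, from 13.7% to 16.0%. Before normalisation for position it was 6.32% and 5.06%, a smaller difference between the arrays. The 6-mers were joined with their reverse complements, so the fit could not tell the printed strand from the other. Base numbers of the printed strand alone accounted for 15.4% of the variance on the SIX6 array and 21.3% on the TFAP2A array, without cross-validation. R2 therefore does not compare the sites of the 2 proteins alone. The highest SIX6 coefficients were those of ATATCC, 0.27 (SE 0.03) log2 per copy, ATGATA with 0.21, GATACC with 0.21, GTATAC with 0.20 and GTGATA with 0.20. The lowest were TTATAA with -0.21 (SE 0.04), CACGTG with -0.20, TGATAA with -0.18, CACGTA with -0.16 and GAGGTA with -0.15. Each coefficient holds the other 6-mers fixed, and many of these overlap it, so a low one need not mean a low signal. The CACGTG class was at percentile 93.3 of matched and 64.4 of unmatched lists on the SIX6 array. TGATAA holds GATA. For TFAP2A the highest were GCCCGC with 0.12 (SE 0.03), CCCCTA with 0.12, CCCCGC with 0.11, CCCGAG with 0.11 and AGTCAT with 0.10. The lowest were CGGCCG with -0.15 (SE 0.04), CGCCCG with -0.15, CGGCGC with -0.13, CGGGCC with -0.13 and CGGGCA with -0.12. On the SIX6 array the highest TFAP2A 6-mers had coefficients from 0.01 to 0.09 and the lowest from -0.11 to -0.06. A part of these values was thus common to both arrays.

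In all, 170 coefficients on the SIX6 array and 27 on the TFAP2A array lay more than 3 SE above the median coefficient, and 96 and 40 lay more than 3 SE below it. On the 892 control sequences, which the fit had not used, predicted and measured log2 intensity correlated at r = 0.632 for SIX6 and r = 0.438 for TFAP2A. The coefficients of the 2 arrays correlated at r = 0.613 across 6-mers, which are not independent replicates.

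Both proteins gave more signal where the core lay near the common end of the probe. On the SIX6 array, probes with 1 TGATAC had a mean log2 intensity of 0.24 (SE 0.02, 209 probes) with the core near the free end, 0.55 (SE 0.03) in the middle and 0.74 (SE 0.03, 187 probes) near the common end. Free end minus common end was -0.49 (SE 0.04), against -0.07 for the same probes on the TFAP2A array. On the TFAP2A array, probes with 1 GCCNNNGGC rose from 0.12 (SE 0.05, 89 probes) to 0.45 (SE 0.07, 99 probes), a difference of -0.32 (SE 0.08). On the SIX6 array that difference was 0.18. TGATAC on the printed strand gave 0.10 (SE 0.03) more than on the other strand.

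**Figure D4:**
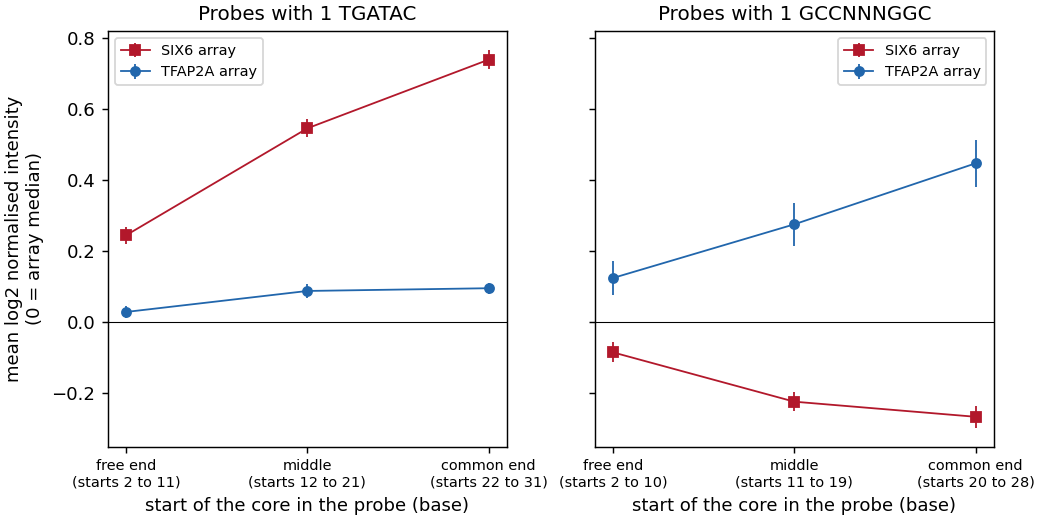
Mean log2 normalised intensity, with 0 at the array median, of probes with 1 TGATAC (left) or 1 GCCNNNGGC (right) by where the core starts, in bases from the free end, on the SIX6 array (red squares) and the TFAP2A array (blue circles), with SE over probes. SIX6 rises from 0.24 to 0.74 on the left, and TFAP2A from 0.12 to 0.45 on the right.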

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

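The control sequences were outside the planned comparisons, and the limit of 1 used for them was chosen after the values were seen. On the SIX6 array 8 of the 892 control sequences had a mean log2 intensity above 1 over the array median. These sequences were outside the comparisons of bound 8-mers and served above only for the spread of duplicate spots and for a check of the 6-mer regression. The highest mean was 1.31. The same 8 sequences had a mean of 0.36 on the TFAP2A array, where none of the 892 was above 1. Of the 8, 5 held TATC or GATA, as did 160 of all 892.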

How the results depend on the processing

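The base-number removal, disjoint rows, second start 8-mers and separate ranking or picking rows were chosen after seeing the data. Of the values that answer a comparison, 46 stayed within their spread or within 1.5 times the count and 43 moved. None changed sign. For r the spread was the difference between odd and even rows. Among class percentiles and counts, 98 stayed and 26 moved. The number of bound SIX6 8-mers was 315, 815 and 1 at thresholds of 0.40, 0.35 and 0.49, and 105, 204 and 5 for TFAP2A, and 3 and 10 passed on both arrays at 0.40 and 0.35. With the Z-score above 4 the numbers were 522, 114 and 3. The SIX-type share was 30.5% at 0.40 and 26.2% by Z-score, and the AP-2-type share 35.2% and 26.3%. Before normalisation 33 SIX6 8-mers (31 of the 65 among them) and 24 TFAP2A 8-mers passed, the SIX6 median single-base change was -0.86, R2 was 6.32% and 5.06%, and the TGATAC position difference was -0.41. From odd rows 56 TFAP2A 8-mers passed and r was 0.427, and from even rows 1 8-mer passed on both arrays. With base numbers removed r was 0.402, and over disjoint rows 0.229 and 0.223. The TFAP2A median single-base change was -0.50 from means of log2, -0.59 from the 8-mer with the highest median and -0.42 from the second start. Picked on odd rows and measured on even rows, the best 8-mer had a median change of -0.0592 for SIX6, with 0 intervals below 0. For TFAP2A the change was -0.28, with 1 interval below 0. The other way round the values were -0.0876 (1) and -0.24 (8). The start 8-mer changed together with the rows, except for TFAP2A picked on even rows, so these moves are not those of the rows alone. With sites next to the common end left out, 7 SIX6 changes had an interval below 0, with fewer probes. The spacer difference was 0.28 and 0.77 with separate ranking rows. TFAP2A R2 was 17.8% with 5-mers and 12.4% on untransformed intensity. Except where the construction shows it, the cause was not tested. The SIX6 8-mer with the highest median was the main one, so that setting moved nothing there, and the setting without flagged probes was not run. No paired analysis was possible because each protein had 1 array. Signal over background limits the folds: negative control spots had 76.5% and 46.8% of the intensity around them, and dark corner spots 96.5% and 61.0%.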

Other observations

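The tests of base composition on the correlation between the arrays and of a run effect common to both arrays and the disjoint rows were chosen after the result was seen, as were the palindromes and control orientations described here. Of the 256 palindromic 8-mers, 9 were bound by SIX6, or 3.52%, against 56 of 32640 others, or 0.172%. Beside GGATATCC, GATATATC and TGATATCA these were CGATATCG with an E-score of 0.469, TATCGATA with 0.469, CGGATCCG with 0.468, ATACGTAT with 0.455, GTGATCAC with 0.453 and ATATATAT with 0.452. They were named after their values were seen. Their E-scores on the TFAP2A array lay between 0.0151 and 0.202. TFAP2A bound 2 palindromes, CCCCGGGG and CCTCGAGG.

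The frequency of palindromes in the SIX6 set was weighed against 2 explanations. A palindrome lies on a median of 18 probes, and fewer probes widen an E-score, but with all other 8-mers thinned to 18 probes 0.236% of them passed. That argues against probe number as the cause. A palindrome offers a site on each strand, and the sites could add up without any contact between 2 proteins. Probes with these palindromes lay 0.107 log2 (SE 0.030, 162 probes) above the additive 6-mer regression, between the bounds of 0.10 and 0.20 set beforehand. They were picked on these same probes, which raises that value, and in a split chosen later, picked on one set of rows and measured on the other, palindromes lay 0.07 (SE 0.02, 197 probes) above it. The value of 0.07 lies within the bound of 0.10 that was set for simple addition. It covers 19 palindromes, 9 of them among the bound ones above, and no such value is given for other bound 8-mers. Simple addition and a joint effect cannot be told apart.

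E-scores of the 2 proteins correlated across 8-mers, while none was above 0.45 on both arrays, where 0.0731 would be expected from independent sets. Above 0.35, 10 passed on both arrays against 5.05 expected. Over disjoint probes r fell to 0.226, from 0.445 over the same rows. Even within 1 array, odd and even rows correlated at only r = 0.513 for SIX6 and r = 0.321 for TFAP2A. The same rows share the bases around each 8-mer as well as the spots. The fall may come from either, and this test cannot tell them apart. The part left over disjoint probes does not rest on shared spots. Removing the numbers of A, C, G and T on the printed strand, which accounted for 15.4% of the variance on the SIX6 array and 21.3% on the TFAP2A array, lowered r from 0.480 to 0.402, which argues against base composition as the whole cause. DNA amount, the antibody and GST stay open, because Cy3 held no values and no array without protein was analysed here. No biological explanation was tested.

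Runs of C or G were frequent among the 8-mers bound by TFAP2A: of the 11 bound without an AP-2-type class, 10 held GGGGG. Over the 202 such 8-mers with no AP-2-type class the median E-score was 0.376 on the TFAP2A array and 0.0974 on the SIX6 array (0.372 and 0.375, against 0.114 and 0.0609, from odd and even rows), which argues against a run effect common to both arrays as the whole cause. A common part stays open, because random lists matched on G and C to the 208 GGGGG 8-mers had medians of -0.112 on the TFAP2A array and -0.144 on the SIX6 array. Without probes holding GCCNNNGG, CCCNNNGG or GCCNNGG the recomputed median was 0.377 against 0.378 before. With printed-strand base numbers removed by a linear fit it was 0.344. Neither sites of those patterns nor a linear effect of base numbers accounted for the high scores. Other forms of the site and local base content were not tested. Binding of TFAP2A to C runs is a hypothesis for the rest, while the antibody, GST or structures of printed runs could account for the common part, with 1925 probes printed with CCCCC against 20 with GGGGG.

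The 2 orientations of a control sequence differed in signal. Over 434 sequence pairs the orientation difference had an SD of 0.39 log2 on the SIX6 array and 0.36 on the TFAP2A array, 3.45 and 3.14 times that predicted from duplicate spots. The differences of the 2 arrays correlated at r = 0.617, and they correlated with the number of T minus A on the printed strand at r = 0.652 and r = 0.595. With the number of G minus C they correlated at r = -0.181 on the SIX6 array and r = -0.636 on the TFAP2A array.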
